A study of Danio rerio with 76 samples.

How the data were processed

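The values were the authors' own. Per the file headers, 52 mRNA-seq libraries held FPKM (fragments scaled to transcript length and library size) made by the authors, in a pair of tables of 11631 and 14638 genes with 1 replicate of each group in each. Of these genes 11623 were in both tables and were used. FPKM columns summed to between 0.292 and 1.42 (in units of 1e6). The signal values of the 4 morpholino libraries at 4 h, as deposited by the authors, summed to between 16.76 and 16.77 (in units of 1e6) in each library and rose with gene length. They were therefore read as signal scaled by the authors to a common total and not as FPKM, although the sheet is named FPKM and the plan had assumed FPKM. The submitters' processing notes name TopHat2 2.0.14, Bowtie2, HOMER and danRer10 without role or order, and the peak caller is not given in the sources used here.

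Columns were matched to samples by header, since the column letter in 2 labels pointed elsewhere. Per-sample columns that matched no sample (5) were not used, and 11 gene names in the second table had been turned into dates. Gene-level ratios of pull-down to input were not computed. Classes were those of the authors' deposited table (maternal 5211, semi-stable 3948, zygotic 2472 genes), used in place of classes planned from the input libraries. Marks came from the authors' deposited table too: a gene counted as m6A-marked with an m6A-seq peak at 0, 2 or 4 h. Genes with no entry there counted as unmarked, and this rule replaced a narrower one after the first output had been seen; the narrower one was kept as an alternative.

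Genes with FPKM of at least 1 in at least 2 libraries of a fit were kept (scaled signal of at least 10 for the morpholino libraries, in place of the planned FPKM rule). Limma was fitted to log2(value + 1) with a group term and empirical Bayes with trend, separately for the maternal, maternal-zygotic, late and 4 h morpholino series, and jointly for the difference between maternal and maternal-zygotic effects. All fits but the 4 h morpholino fit held a term for the replicate set, because the tables may have been scaled separately. The 4 h morpholino replicates sit in separate tables too, but their fit was kept without the term, as planned, and the fit with it is an alternative. P-values were two-sided from limma's moderated t, adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. No normalization was added to the authors' scaling.

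Gene lists (22) were fixed before the values were seen. The lists, the authors' classes and the m6A-marked set made 26 sets, tested in 14 comparisons by camera with a preset correlation of 0.01. These p were adjusted together with those of marked against unmarked maternal genes. Fry and camera with an estimated correlation were run beside it. Genes were named by a rule: the targeted gene, up to 8 per direction by size of change among those past the threshold with a mean FPKM of at least 5 in the higher group and the same direction in both replicate sets, up to 4 per list among those past the threshold, and the 3 with the lowest p for a list with none. Loci without a symbol were skipped. The text names a part of these. MicroRNA loci are not named singly, because of 447 pairs of gene and group with 1 replicate listed at 0 and the other at 20 FPKM or more, 430 were microRNA loci (96.2%).

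Peaks were compared between times with bedtools, by strand, at an overlap of at least 1 base. A table of the GRCz12tu assembly served only for gene names and neighbours.

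The steps were run on simulated values with 200 changed genes, drawn only from genes with a high simulated level. The recovery given here therefore holds for such genes, and recovery of genes at lower levels was not tested. At a log2 change of −2 and 2 the fit recovered 62% and 70% in the 0 h design of the maternal series, 90% and 96% in the 6 h design of the maternal-zygotic series, and 100% and 96% in the 24 h late design. For changes of −1 and 1 these were 6% and 4%, 62% and 58%, and 66% and 70%. The 4 h morpholino fit, without a term for the replicate, recovered 0% at each size. Limma's camera gave a set p of 2.26e-11 or lower for a simulated set of 15 genes shifted by 1 in each design. The simulated genes varied independently of each other. This step therefore does not test the preset correlation, on which the set calls in the real data rest. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.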

Results

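The series followed zebrafish embryos through the hours in which maternal mRNA is cleared and zygotic genes come on, and asked how m6A, a methyl mark on mRNA, and ythdf2, a protein that reads it, take part. It held 76 samples. m6A was mapped by m6A-seq (antibody pull-down of mRNA fragments) and by m6A-CLIP (the same with crosslinking, for finer positions). Each method had 1 pull-down and 1 input sample at 0, 2, 4, 6 and 8 h, so the m6A data have no replicates. mRNA was sequenced in 28 groups of 2 libraries. Wild type and maternal ythdf2 null embryos were taken at 0, 2, 4, 6 and 8 h, and wild type and maternal-zygotic ythdf2 null at 6, 8, 12 and 24 h and at a somite stage. Control and ythdf2 morpholino (MO) embryos were taken at 4 h, and wild type with control MO and maternal ythdf2 null with ythdf2 MO at 24, 36 and 48 h. The depth of these libraries is unknown, since FPKM carry no read counts. Replicates correlated over genes at r from 0.942 to 0.986 (genes are not independent replicates). Nothing in the labels says that they came from separate clutches, so p-values measure only the spread between these samples. Changes below are log2 fold changes ± SE on the log2(FPKM + 1) scale, levels are mean ± SD with n = 2 per group, and adjusted p come from limma with Benjamini-Hochberg adjustment. In comparisons of null or morpholino embryos with their controls, rose and fell mean higher and lower than the control, and not a change over time.

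The targeted gene came first. Maternal null embryos had ythdf2 at 2.16 ± 0.716 FPKM at 0 h against 68.9 ± 22.4 in wild type (−4.45 ± 0.71, adjusted p = 0.00215), and at 1.59 ± 0.656 at 2 h against 72.3 ± 29.1 (−4.79 ± 0.71, adjusted p = 0.00266). At 4 h replicate 1 of the maternal null had ythdf2 at 7.59 FPKM, but the library labelled maternal null 4 h replicate 2 had 97.4, within the wild-type values of 140.5 and 83.1. At 6 and 8 h maternal null levels were 93.2 ± 15.8 and 79.6 ± 1.48 FPKM and did not pass (−0.87 ± 0.71 and −0.69 ± 0.71). Maternal-zygotic null embryos had lower ythdf2 at 6 h (−1.90 ± 0.29), 8 h (−1.63 ± 0.29), 12 h (−2.39 ± 0.29), 24 h (−2.12 ± 0.29) and the somite stage (−1.68 ± 0.29). At 6 h their replicates had ythdf2 at 12.9 and 59.8 FPKM against 67.1 and 172.1 in the wild type of the same tables. The second null library lay near 67.1 only across tables, which may have been scaled separately, and below the 172.1 of its own table. It correlated best with wild type 6 h replicate 2 (r = 0.9624). In maternal null embryos with ythdf2 MO, ythdf2 mRNA rose at 24 h (1.46 ± 0.12), 36 h (1.62 ± 0.12) and 48 h (1.46 ± 0.12), from 29.4 ± 0.0323 to 83.1 ± 8.58 FPKM at 24 h. After ythdf2 MO alone the scaled signal was 6197 ± 719 against 6605 ± 412 (−0.10 ± 0.14, adjusted p = 1). These values measure mRNA and not protein, so they do not check the labels of the morpholino libraries.

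**Figure D1:**
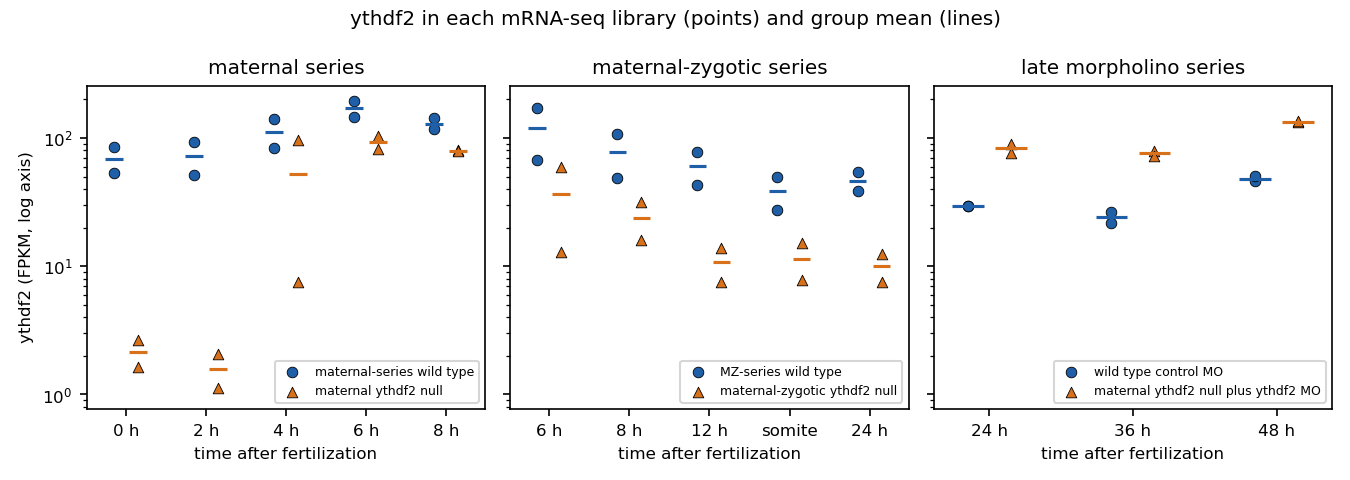
The level of ythdf2 mRNA in each FPKM library by time after fertilization, with a point per library and a line per group mean. The library labelled maternal null 4 h replicate 2 had 97.4 FPKM.

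In wild-type embryos single egg transcripts fell and single patterning genes rose from 4 h on. The deadenylation adaptor btg4 fell from 576.1 ± 95.6 FPKM at 0 h to 182.5 ± 35.2 at 4 h (−1.66 ± 0.38), 6.82 ± 1.97 at 6 h (−6.22 ± 0.38) and 2.74 ± 1.09 at 8 h (−7.29 ± 0.38). The germ plasm organizer buc fell (−1.69, −5.73 and −7.54 at these times), as did slbp2, which binds histone mRNA in the egg (−1.94, −5.47 and −7.58). At 8 h cldnd (−8.44) and cth1 (−7.70) had fallen furthest among the genes named. Among the genes that rose at 4 h were nnr (8.45 ± 0.40), the ventral regulator vox (7.97 ± 0.32), the mesoderm regulator tbx16 (7.87 ± 0.38), the keratin krt18 (7.25 ± 0.32) and sox19a (6.46 ± 0.32). By 6 h krt18 (10.11 ± 0.32), apoeb (9.80 ± 0.43) and aldob (9.76 ± 0.38) had risen furthest, and by 8 h afp4 (10.88 ± 0.69). The m6A readers moved apart: igf2bp1 rose from 20.6 ± 8.80 FPKM to 185.2 ± 4.66 at 6 h and 355.4 ± 65.2 at 8 h, while ythdf3 fell from 33.2 ± 16.7 FPKM to 6.49 ± 2.32 at 6 h. The targeted ythdf2 did not pass at 4, 6 and 8 h (0.68 ± 0.71, 1.33 ± 0.71 and 0.94 ± 0.71).

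Counts of changed wild-type genes grew with time. Against 0 h, limma passed 0 of 11023 genes at 2 h (140 at unadjusted p under 0.05), 1652 at 4 h (904 higher, 748 lower), 6622 at 6 h (2919 higher, 3703 lower) and 7270 at 8 h (3257 higher, 4013 lower). At 4 h quantile normalization turned the split to 1669 higher and 2094 lower. The median of all genes lay at −0.171 at 6 h and −0.222 at 8 h (−0.117 and −0.128 after quantile normalization, −0.205 and −0.255 with a pseudocount of 0.1), and every fold named for these times exceeds that shift. With 1 library left out the 4 h count was 800 without wild type 4 h replicate 1 and 1492 without wild type 0 h replicate 2, and the 2 h count reached 36 without wild type 0 h replicate 2. The majority turned without wild type 0 h replicate 2 at 4 h (734 higher, 758 lower), without wild type 6 h replicate 1 at 6 h (2910 and 2587), and at 8 h without wild type 8 h replicate 1 (3172 and 2930) or wild type 0 h replicate 1 (3106 and 3077). Without wild type libraries in turn, btg4, ca15b and buc did not pass every time at 4 h. The other genes named as changed did at the times given, while ythdf2 had no call.

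m6A peaks lay on mRNAs of every class, and early zygotic mRNAs gained them as they appeared. Per the authors' deposited table, buc had 3 m6A-seq peaks at 0, 2 and 4 h and none at 6 and 8 h, sox19a had none at 0 and 2 h and 3 at 4 h, and ythdf2 itself had 1, 2, 3, 3 and 3. The shares that follow are of genes with an entry for m6A peaks (annotated genes), which in the authors' deposited table were 3535 of 5211 maternal, 1283 of 2472 zygotic and 2835 of 3948 semi-stable genes. In the same authors' deposited table, 40.7, 25.6, 57.3, 20.1 and 31.5% of annotated maternal genes had an m6A-seq peak at 0, 2, 4, 6 and 8 h. Each step went the way of the length of the peak lists. Yet lists of similar length gave lower shares later: 5182 peaks at 0 h and 5244 at 6 h, and 7875 at 4 h and 7986 at 8 h. By m6A-CLIP the shares of annotated maternal genes were 70.9, 81.4, 65.6, 31.8 and 34.7% in the authors' deposited table. By m6A-seq, annotated zygotic genes went from 10.8% at 0 h to 71.8% at 8 h in the authors' deposited table. By m6A-CLIP they went from 19.2% to 75.3% in the authors' deposited table. Annotated semi-stable genes went from 46.7% to 75.7% by m6A-seq, but only from 66.4% to 69.8% by m6A-CLIP, in the authors' deposited table. The m6A-seq list was also longer at 8 h (7986 peaks) than at 0 h (5182). Of 49 annotated early zygotic patterning genes, 16 had an m6A-seq peak at 4 h and 37 at 8 h in the authors' deposited table, and of 13 annotated germ plasm and germ cell genes 9, 3, 8, 5 and 4 had one at 0, 2, 4, 6 and 8 h. All 6 annotated m6A writers carried an m6A-seq peak at 0, 4, 6 and 8 h in the authors' deposited table. Both methods marked 2394 of 7653 annotated genes at 0 h in the authors' deposited table, against 1758 for independent marks within these genes. Genes without an entry were taken to have no peak in any list. The shares above therefore lie above those over all genes of a class. The value for independent marks would likewise be lower over all genes. A gene needs enough mRNA for a peak to be called, so these shares follow expression too.

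**Figure D2:**
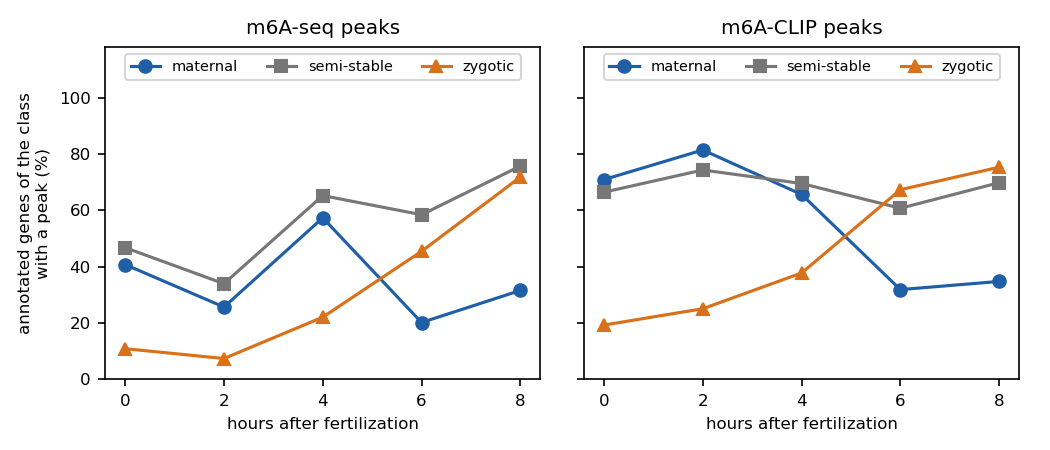
Percent of annotated genes with an m6A peak by hours after fertilization, for the authors' maternal, semi-stable and zygotic classes and for m6A-seq and m6A-CLIP. Annotated zygotic genes went from 10.8% to 71.8% by m6A-seq.

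The peak lists varied in length from time to time. m6A-seq listed 5182 peaks at 0 h, 2952 at 2 h, 7875 at 4 h, 5244 at 6 h and 7986 at 8 h, with mean widths of 162.5 to 168.2 bases along transcripts. m6A-CLIP listed 24474, 34928, 25482, 18189 and 27025 peaks of 29.9 to 31.1 bases on the genome. Of the m6A-seq peaks at 2 h, 94.2% (95% Wilson interval 93.3 to 95.0) overlapped a peak at 4 h by at least 1 base, and of those at 6 h 84.8% (83.8 to 85.8) overlapped one at 8 h. From the longer list to the shorter, 35.8% of peaks at 4 h overlapped one at 2 h and 55.6% at 8 h one at 6 h, and from 0 to 2 h it was 48.8%. Of m6A-CLIP peaks at 0 h, 60.8% (60.1 to 61.4) overlapped one at 2 h. These intervals cover counting error only, and with 1 list per time no replicate check exists.

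At 0 h, in RNA laid down by the mother, maternal null and wild type embryos already differed in single genes. The somite regulator dmrt2a (29.7 ± 10.5 against 0.512 ± 0.235 FPKM; 4.31 ± 0.65, adjusted p = 0.00162), the neural crest regulator tfap2a (3.75 ± 0.54), the melatonin enzyme aanat1 (3.75 ± 0.74) and the actin-binding tmsb4x (3.42 ± 0.50) were higher in the null. The immunoglobulin-domain gene dicp1.3-4 (0.0725 ± 0.0461 against 20.1 ± 5.91 FPKM; −4.27 ± 0.48, adjusted p = 0.0003), tmem45a (−4.14 ± 0.66), shisa2 (−3.66 ± 0.39) and the autophagy gene becn1 (−3.61 ± 0.65) were lower. Of egg genes, zar1 was higher (1.88 ± 0.44), and of decapping genes dcp1b was lower (−2.30 ± 0.45). The same directions held at 2 h for dmrt2a (3.70 ± 0.65), aanat1 (3.90 ± 0.74), shisa2 (−4.12 ± 0.39), tmem45a (−4.45 ± 0.66), becn1 (−3.56 ± 0.65) and dicp1.3-4 (−3.52 ± 0.48), and there fgfr4 (2.53 ± 0.32), her2 (2.72 ± 0.34) and id1 (2.74 ± 0.37) were higher as well.

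Limma passed 329 of 11023 genes at 0 h (133 higher, 196 lower) and 224 at 2 h (64 higher, 160 lower). Both comparisons passed 50 genes as higher against 0.772 for independent lists, and 110 as lower against 2.84, with r = 0.864 over genes. These comparisons are not independent, since they share 1 fit. Libraries at 0 and 2 h of the same genotype and replicate set correlated at r from 0.9834 to 0.9966. Replicates of these groups correlated at r from 0.968 to 0.983. The overlap is therefore no separate support for the 0 h differences. Quantile normalization gave 385 higher and 434 lower at 0 h and 186 and 253 at 2 h. With 1 library left out, from 42 genes (23 higher, without maternal null 0 h replicate 2) to 380 (without wild type 0 h replicate 2) passed at 0 h, and from 7 (5 higher, without maternal null 2 h replicate 2) to 166 (without wild type 2 h replicate 2) at 2 h. Without the replicate set as a term 190 and 147 passed, and without the library labelled maternal null 4 h replicate 2, which shares the estimate of the spread, 540 and 462 did. Each library left out in turn kept dmrt2a, tfap2a, tmsb4x, dicp1.3-4 and shisa2 past the threshold at 0 h and fgfr4, her2 and shisa2 at 2 h; the other genes named lost it at least once, ythdf2 included.

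Few lists moved as a whole before 4 h. Yolk syncytial layer and liver-type transport genes had a median of 0.832 at 0 h (camera adjusted p = 0.000553; adjusted p = 0.811 with an estimated correlation). At 2 h it was 0.781 (camera adjusted p = 0.000327; adjusted p = 0.811 with an estimated correlation). None of its 15 members passed, over all genes or adjusted over the list alone, and its medians differed between the replicate sets (0.227 and 1.03 at 0 h). Skeletal muscle genes had a median of 0.899 at 2 h (camera adjusted p = 0.00792; adjusted p = 0.874 with an estimated correlation). It was 0.036 in the first replicate set and 1.301 in the second, and 1 of 12 rose adjusted over the list alone. Camera sets a list against all other genes at a fixed low correlation between genes. Fry asks only whether a list's genes move on balance in 1 direction, and its adjusted p were 0.252, 0.259 and 0.289. Among the authors' classes, 125 of 5009 maternal genes were lower and 44 higher in the null at 0 h. The authors may have set these classes on related libraries, so they are not independent evidence.

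At 4 h the maternal null comparison rests in part on the library labelled maternal null 4 h replicate 2, whose ythdf2 level was that of wild type. The endosome gene plekhf1 (4.49 ± 4.13 against 33.5 ± 9.28 FPKM; −2.86 ± 0.40, adjusted p = 0.00902), the sulfate transporter slc26a1 (−2.35 ± 0.33, adjusted p = 0.00902) and cyb561d1 (−2.25 ± 0.41, adjusted p = 0.0486) were lower in the null libraries under their labels. Limma passed 9 of 11023 genes (1 higher, 8 lower). With the term for the replicate set fitted within each time 0 passed. Quantile normalization gave 54 higher and 68 lower, and leaving out 1 library gave from 0 (without wild type 4 h replicate 2) to 336 (without the library labelled maternal null 4 h replicate 2), with none of the 3 genes past the threshold every time. Of zygotic genes, fgf3 (−1.64 ± 0.33, adjusted p = 0.0808), mxtx1 (−1.75 ± 0.45, adjusted p = 0.172), krt18 (−1.20 ± 0.32, adjusted p = 0.2) and mcm6 (−1.50 ± 0.33, adjusted p = 0.119) did not pass. Egg transcripts did not pass either, with btg4 at 0.65 ± 0.38 and buc at 0.58 ± 0.35.

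As groups, zygotic genes lay lower and maternal genes higher at 4 h in maternal null embryos. Early zygotic patterning genes had a median of −0.485 (camera adjusted p = 8.45e-10; adjusted p = 0.811 with an estimated correlation). Of 50 measured none passed over all genes, while 8 fell and 1 rose adjusted over the list alone. Enveloping layer and periderm genes had a median of −0.959 (camera adjusted p = 2.43e-07; adjusted p = 0.811 with an estimated correlation). Of these, 6 of 16 fell adjusted over the list alone. Replicate set 1 carried both, with medians of −0.975 and −1.71 there against 0.019 and −0.189 in set 2, which holds the library labelled maternal null 4 h replicate 2. The authors' maternal class had a median of 0.167 (camera adjusted p = 5.06e-07; adjusted p = 0.999 with an estimated correlation). Their zygotic class had one of −0.138 (camera adjusted p = 6.1e-09; adjusted p = 0.811 with an estimated correlation). The fry adjusted p of these 4 groups were between 0.1 and 0.974.

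Embryos with ythdf2 MO at 4 h had patterning, enveloping layer and zygotic genes lower and maternal genes higher as groups, as in maternal null replicate set 1. Early zygotic patterning genes had a median of −0.379 (camera adjusted p = 5.1e-12; adjusted p = 0.811 with an estimated correlation). Of them aplnrb (−0.40 ± 0.20), mxtx2 (−0.21 ± 0.11) and fgf17 (−0.38 ± 0.21) did not pass. Enveloping layer genes had a median of −0.627 (camera adjusted p = 0.00413; adjusted p = 0.999 with an estimated correlation). P53 response genes had one of −0.137 (camera adjusted p = 0.0219; adjusted p = 0.811 with an estimated correlation), against 0.113 and no call in maternal null embryos at 4 h. Maternal genes lay at 0.075 (camera adjusted p = 3.28e-11; adjusted p = 0.999 with an estimated correlation). Zygotic genes lay at −0.14 (camera adjusted p = 4.27e-19; adjusted p = 0.811 with an estimated correlation). The deadenylase parn (−0.75 ± 0.20), buc (0.35 ± 0.31) and pou5f3 (−0.12 ± 0.16) did not pass. Limma passed 0 of 10587 genes (13 at unadjusted p under 0.05) in a fit without a term for the replicate, and this count and these calls depend on that choice. With that term 998 passed (554 higher, 444 lower). It pairs libraries of the same number, and no label says that they were paired. In simulated data this fit, without that term, recovered 0% of genes changed by a log2 of 2, so its count says little about single genes. The MO and maternal null effects correlated over genes at r = 0.349 and share no library. The maternal null effect here includes the library labelled maternal null 4 h replicate 2, and its replicate sets correlated at r = −0.00258. The r of 0.349 can also follow from the class shifts given above, so it adds no separate support.

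At 6 and 8 h, genes of the p53 response were higher in embryos of maternal null mothers. The p53 target phlda3 rose to 71.8 ± 26.4 against 2.38 ± 0.105 FPKM at 6 h (4.38 ± 0.40, adjusted p = 8.16e-06) and 33.3 ± 9.95 against 2.36 ± 0.669 at 8 h (3.33 ± 0.40, adjusted p = 0.000148). The forkhead factor foxo3b (3.29 ± 0.37 and 3.04 ± 0.37), the caspase casp8 (2.86 ± 0.41 and 2.89 ± 0.41) and the ubiquitin-like isg15 (3.07 ± 0.40 and 2.86 ± 0.40) were higher than wild type at both times. The cell-cycle inhibitor cdkn1a was higher at 6 h (2.61 ± 0.40). The wild-type level of casp8 had itself fallen by 8 h, so its difference need not be a rise over time in the null. The membrane gene eva1ba fell at both (−3.36 ± 0.28 and −3.61 ± 0.28). At 6 h the blood and vessel regulator lmo2 rose (2.21 ± 0.29), and the crystallin crygm3 and the troponin tnni2b.2, each listed at 0 in the second null library, fell (−2.81 ± 0.33 and −2.77 ± 0.35). At 8 h the plasma protein genes apoa4b.1 (−2.69 ± 0.34), serpina1l (−1.97 ± 0.28) and serpina1 (−1.77 ± 0.29), the clock repressor bhlhe41 (−2.44 ± 0.25) and the heart regulator gata4 (−1.13 ± 0.24) fell.

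Of 15 p53 response genes, 6 were higher than wild type at 6 h and 7 at 8 h, casp8 among them, and 11 at each time adjusted over the list alone. Their medians were 1.14 and 1.64 (camera adjusted p = 3.55e-16 and 1.15e-20; adjusted p = 0.647 with an estimated correlation at both times; fry adjusted p = 0.0052 and 0.00405). Of 15 yolk syncytial and transport genes 3 fell at 8 h and 12 did not pass, and 5 fell adjusted over the list alone (median −0.339, camera adjusted p = 3.1e-07; adjusted p = 0.811 with an estimated correlation). Among 10 interferon response genes, isg15 and ifit8 rose at both times (2 rose and 1 fell at 6 h and 2 rose at 8 h, adjusted over the list alone). The list's median lay below 0 (−0.141 and −0.146) and its mean above it (0.34 and 0.275), and camera gave no call. Of 6 erythroid genes only cahz fell at 6 h, over all genes and adjusted over the list alone. Limma passed 126 of 11023 genes at 6 h (68 higher, 58 lower) and 176 at 8 h (65 higher, 111 lower), and quantile normalization gave 274 higher and 290 lower at 6 h and 262 and 283 at 8 h. With a pseudocount of 0.1 the majority turned at both times, to 39 higher and 45 lower at 6 h and 34 and 31 at 8 h.

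The range with 1 library left out was 45 genes (without maternal null 6 h replicate 2) to 101 (33 higher and 68 lower, without wild type 6 h replicate 1) at 6 h, and 63 (without maternal null 8 h replicate 2) to 117 (without wild type 8 h replicate 1) at 8 h. At each of these steps phlda3, foxo3b, isg15, casp8, cdkn1a, eva1ba, crygm3, tnni2b.2 and lmo2 at 6 h, and phlda3, foxo3b, casp8, isg15, eva1ba, apoa4b.1, serpina1l and bhlhe41 at 8 h, passed, whereas ifit8, cahz, gata4 and serpina1 did not. The change since 0 h itself differed from wild type for 77 genes at 6 h (40 higher, 37 lower) and 131 at 8 h (53 higher, 78 lower), with the egg-borne dmrt2a dropping out (−4.37 at 6 h) and shisa2 catching up (3.58 at 6 h and 3.64 at 8 h). These counts ranged from 15 (without maternal null 6 h replicate 1) to 114 and from 33 (without maternal null 0 h replicate 2) to 157 (both highest without wild type 0 h replicate 2), and were 161 and 245 without the library labelled maternal null 4 h replicate 2. At 4 h limma passed 0 genes for this difference (567 at unadjusted p under 0.05), and 7 higher and 32 lower after quantile normalization. The 4 h difference includes the library labelled maternal null 4 h replicate 2, whose ythdf2 level was that of wild type.

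**Figure D3:**
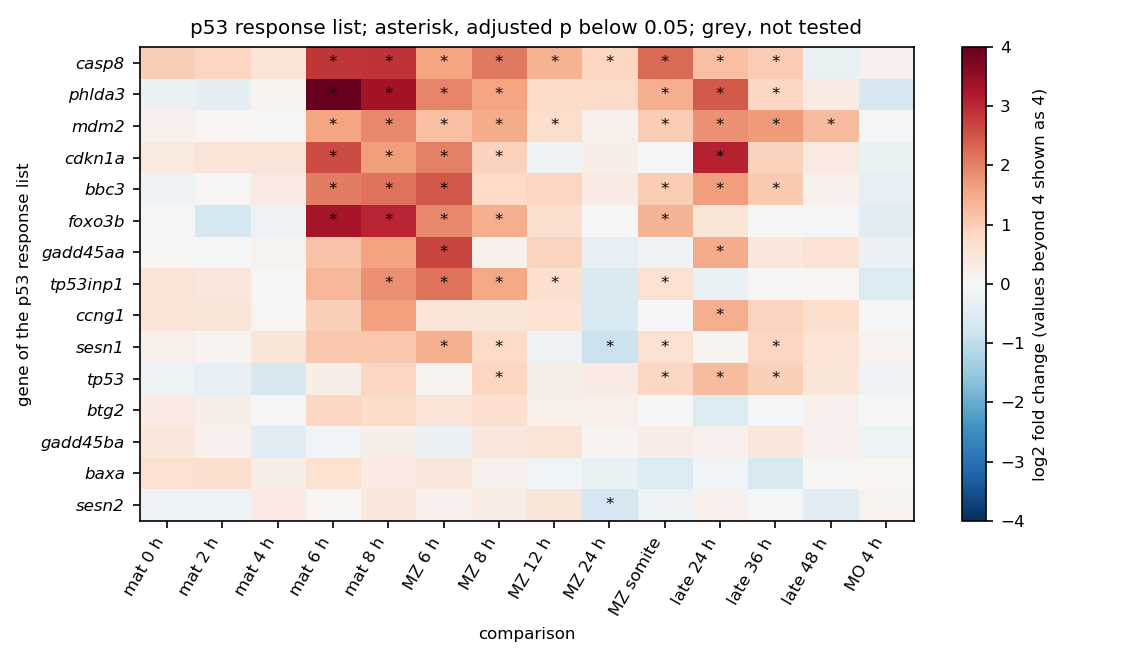
Log2 fold changes of the 15 p53 response genes in each null or morpholino comparison as colors, with an asterisk where the adjusted p passed. The list's medians were 1.14 and 1.64 in maternal null embryos at 6 and 8 h.

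Maternal-zygotic null embryos, compared with their own wild type, showed p53 response genes higher at 6 h and hsp70l and hsp70.1 transcripts far lower. The wild-type level of hsp70l at 6 h was far above that at 8 h, so this contrast also rests on a high wild-type level. The chaperones hsp70l (1.43 ± 1.34 against 121.4 ± 30.8 FPKM; −5.75 ± 0.20, adjusted p = 1.21e-09), hsp70.1 (−5.59 ± 0.34) and hsp90aa1.1 (−2.92 ± 0.47) fell; hsp70l and hsp70.1 are near-identical copies whose split is uncertain. In the p53 response, gadd45aa (2.66 ± 0.27), bbc3, which promotes cell death (2.47 ± 0.30), tp53inp1 (2.18 ± 0.18) and cdkn1a (2.00 ± 0.24) rose, as did the proteasome activator psme1 (2.79 ± 0.26). The embryonic patterning genes eve1 (−2.94 ± 0.49), msgn1 (−2.40 ± 0.65), bmp4 (−1.90 ± 0.26) and the surface-layer regulator grhl1 (−1.95 ± 0.23) fell. Of egg and germ cell transcripts, buc (1.34 ± 0.35), zar1 (1.02 ± 0.24) and tdrd6 (1.41 ± 0.26) were higher. The splicing-related rsrp1 fell from 218.6 ± 97.6 to 20.5 ± 7.89 FPKM (−3.33 ± 0.15).

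Limma passed 1621 of 11142 genes (903 higher, 718 lower; 1333 and 1205 after quantile normalization). Without maternal-zygotic null 6 h replicate 2 the majority turned, to 652 higher and 1153 lower. Of 4943 genes in the authors' maternal class 687 rose and 186 fell (757 and 213 adjusted over the list alone; median 0.193, camera adjusted p = 7.53e-08; adjusted p = 0.939 with an estimated correlation). Of 2349 zygotic genes 90 rose and 284 fell (92 and 295 adjusted over the list alone; median −0.142, camera adjusted p = 8.91e-05; adjusted p = 0.999 with an estimated correlation). The semi-stable class lay at −0.043 (camera adjusted p = 0.0295, and 0.213 after quantile normalization; adjusted p = 0.999 with an estimated correlation), with 126 genes up and 248 down (87 and 183 adjusted over the list alone). Among lists, 9 of 15 p53 response genes rose and 6 did not pass (10 adjusted over the list alone; median 1.45, camera adjusted p = 6.9e-09; adjusted p = 0.811 with an estimated correlation). Of 16 heat shock genes 6 fell, 1 rose and 9 did not pass (8 and 2 adjusted over the list alone; median −0.515, camera adjusted p = 2.74e-05; adjusted p = 0.811 with an estimated correlation). Early zygotic patterning genes split 14 down and 4 up of 50 (18 and 6 adjusted over the list alone; median −0.381, camera adjusted p = 0.00337; adjusted p = 0.999 with an estimated correlation). Of 16 enveloping layer genes 2 fell (6 adjusted over the list alone; median −0.764, camera adjusted p = 0.000117; adjusted p = 0.957 with an estimated correlation). Of 27 cell cycle genes 9 fell and 1 rose (11 and 1 adjusted over the list alone; median −0.319, camera adjusted p = 0.00704, and 0.0601 after quantile normalization; adjusted p = 0.999 with an estimated correlation). Among them were cdk1 (−1.10 ± 0.25) and aurkb (−0.91 ± 0.21). Of 8 zygotic activation factors sox2 fell (−2.44 ± 0.40), sox19b rose (1.27 ± 0.27) and 6 did not pass, with 2 in each direction adjusted over the list alone. Their median lay above 0 (0.212) and their mean below it (−0.034).

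At 8 h hsp70l and hsp70.1 had the opposite sign and p53 response genes were again higher. The chaperone hsp70l rose to 65.9 ± 22.6 against 7.13 ± 2.48 FPKM (3.03 ± 0.20, adjusted p = 2.27e-06) and hsp70.1 by 2.97 ± 0.34. The lipid synthesis regulator mid1ip1b rose most among the genes named (4.39 ± 0.24), and the receptor gene pth2r (−4.26 ± 0.50), spata6l (−3.22 ± 0.44) and eva1ba (−3.17 ± 0.37) fell. Of 15 p53 response genes 8 rose and 7 did not pass, with casp8 at 2.11 ± 0.21 and mdm2 at 1.47 ± 0.19 (10 adjusted over the list alone; median 0.804, camera adjusted p = 1.57e-08; adjusted p = 0.811 with an estimated correlation). The replication genes mcm5 (−1.28 ± 0.19), mcm2 (−1.22 ± 0.19) and mcm4 (−0.94 ± 0.14) and the adhesion gene epcam (−1.64 ± 0.29) fell. Of 6 m6A writers zc3h13 rose (0.80 ± 0.18) and mettl3 fell (−0.87 ± 0.24), and the same 2 passed adjusted over the list alone. Of 15 yolk syncytial and transport genes 3 fell and 12 did not pass (4 adjusted over the list alone; median −0.967, camera adjusted p = 0.0233, and 0.192 after quantile normalization; adjusted p = 0.999 with an estimated correlation), with serpina1l at −1.74 ± 0.28. Of 16 heat shock genes 2 rose and 14 did not pass (2 adjusted over the list alone), with a median of −0.041 and a mean of 0.335.

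Limma passed 1046 genes at 8 h (533 higher, 513 lower). These counts depend on the term for the replicate set: without it 32 genes passed at 6 h and 14 (6 higher, 8 lower) at 8 h. Of genes taken from the naming rule, 8 of 32 at 6 h and 3 of 23 at 8 h passed without it. With each library left out in turn the count was 832 (without wild type 6 h replicate 2) to 1805 (without maternal-zygotic null 6 h replicate 2) at 6 h and 251 (81 higher and 170 lower, without maternal-zygotic null 8 h replicate 2) to 618 (without maternal-zygotic null 8 h replicate 1) at 8 h, where 230 were higher and 382 lower without wild type 8 h replicate 1. Each time, hsp70l, hsp70.1, hsp90aa1.1, gadd45aa, bbc3, tp53inp1, cdkn1a, psme1, rsrp1, eve1, bmp4, grhl1, sox2 and tdrd6 passed at 6 h, but msgn1, buc, zar1, cdk1, aurkb and sox19b did not. At 8 h mid1ip1b, hsp70l, hsp70.1, pth2r, spata6l, eva1ba, casp8, mdm2, mcm5, mcm2, mcm4, epcam and serpina1l passed each time, but zc3h13 and mettl3 did not.

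The maternal and maternal-zygotic effects, which share no library, overlapped in part. At 6 h both passed 26 genes as higher (5.49 for independent lists) and 14 as lower (3.84), and at 8 h 26 as higher (3.15) and 35 as lower (5.24), with r = 0.215 and 0.313 over genes. A direct test of the difference passed 13 of 10542 genes at 6 h and 15 at 8 h. At 6 h hsp70l (−5.81 ± 1.04), hsp70.1 (−5.80 ± 1.11) and aanat1 (−3.20 ± 0.53) were lower in the maternal-zygotic effect, and at 8 h pth2r (−6.03 ± 1.15) and isg15 (−2.92 ± 0.54) were lower and mid1ip1b (3.92 ± 0.57) higher. Counts with 1 library left out were 5 (without maternal null 6 h replicate 1) to 32 (without maternal-zygotic null 6 h replicate 2) genes at 6 h and 2 (without maternal-zygotic null 8 h replicate 2) to 18 (without wild type 8 h replicate 1 of the maternal-zygotic series) at 8 h, and none of these 6 genes passed every time. Quantile normalization gave 29 higher and 49 lower genes at 8 h, against 8 and 7.

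At 12 h single muscle and vessel genes fell in maternal-zygotic null embryos and single early patterning genes rose. The actins acta1a (11.9 ± 5.81 against 54.3 ± 27.7 FPKM; −2.08 ± 0.21, adjusted p = 0.000326), actc1b (−1.45 ± 0.33) and acta1b (−1.12 ± 0.28), the vessel receptor kdr (−1.38 ± 0.23) and lmo2 (−1.52 ± 0.26) fell. Of 12 skeletal muscle genes 3 fell and 9 did not pass, and 3 fell adjusted over the list alone. Of 7 blood vessel and blood stem cell genes 2 fell and 5 did not pass (2 fell and 1 rose adjusted over the list alone), and camera gave no call for either list. The endoderm regulator sox32 (2.09 ± 0.40), the organizer gene gsc (1.27 ± 0.25), vox (0.54 ± 0.14) and the pluripotency factor pou5f3 (1.59 ± 0.21) rose, as did casp8 (1.40 ± 0.21) and dnajc19 (2.43 ± 0.33). Of 50 early zygotic patterning genes 4 rose and 46 did not pass (6 adjusted over the list alone; median 0.246, camera adjusted p = 0.00128; adjusted p = 0.999 with an estimated correlation). Of 15 p53 response genes 3 rose and 12 did not pass (8 adjusted over the list alone; median 0.588, camera adjusted p = 4.37e-05; adjusted p = 0.811 with an estimated correlation). Of 15 yolk syncytial and transport genes 3 fell and 12 did not pass (4 fell and 1 rose adjusted over the list alone; median −0.672, camera adjusted p = 0.0284, and 0.112 after quantile normalization; adjusted p = 0.999 with an estimated correlation). Of 7 hatching gland genes ctslb fell (−1.56 ± 0.40; 2 adjusted over the list alone).

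Limma passed 482 genes at 12 h (159 higher, 323 lower; 467 and 592 after quantile normalization, and 4 and 3 without the replicate set term). Over the 4 libraries left out in turn, from 68 (without wild type 12 h replicate 2) to 172 (without wild type 12 h replicate 1) passed, and of the genes named for 12 h acta1a, casp8, pou5f3 and dnajc19 passed each time, while actc1b, acta1b, kdr, lmo2, sox32, gsc and vox did not. At 24 h the replication genes mcm7 (19.8 ± 17.0 against 108.8 ± 42.3 FPKM; −2.63 ± 0.25, adjusted p = 7.17e-05) and chek1 (−1.21 ± 0.18), the pigment enzyme dct (−1.61 ± 0.26), the lens gene cryba4 (−1.52 ± 0.31), the heme enzyme urod (−0.75 ± 0.18), and apoa1b (−3.14 ± 0.79) fell. Of early and surface genes vox (23.41 ± 10.03 against 8.87 ± 3.88 FPKM), krt18 (1.12 ± 0.20) and the muscle regulator myod1 (1.32 ± 0.33) rose. Of 7 erythroid genes 2 fell and 5 did not pass (6 adjusted over the list alone; median −0.754, camera adjusted p = 0.0118, and 0.0617 with a pseudocount of 0.1; adjusted p = 0.647 with an estimated correlation). Of 50 early zygotic patterning genes 3 rose and 1 fell (3 rose adjusted over the list alone; median 0.147, camera adjusted p = 0.00574; adjusted p = 0.999 with an estimated correlation). Of 12 neural crest and pigment genes 2 fell and 10 did not pass (5 down and 1 up adjusted over the list alone; no camera call, fry adjusted p = 0.00173). Unlike at 6, 8 and 12 h, of 15 p53 response genes sesn1 (−0.86 ± 0.17) and sesn2 (−0.68 ± 0.19) fell, only casp8 rose (0.87 ± 0.21) and 12 did not pass (3 down and 2 up adjusted over the list alone; median 0.107, no camera call). Limma passed 1082 genes at 24 h (342 higher, 740 lower; 1213 and 1298 after quantile normalization, and 8 and 7 without the replicate set term). Of genes taken from the naming rule, 1 of 22 at 12 h and 1 of 19 at 24 h passed without that term. Dropping 1 library gave 435 (without wild type 24 h replicate 2) to 811 (without maternal-zygotic null 24 h replicate 1), and mcm7, chek1, dct, vox and krt18 passed each time, unlike cryba4, urod, apoa1b, myod1, sesn1, sesn2 and casp8. With a pseudocount of 0.1 the median of all genes at 24 h was −0.105, which the folds named here exceed.

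At the somite stage wild type embryos were collected at 16 h and maternal-zygotic null embryos at 17.5 h. The labels give both groups the same range of somites, so they were matched by stage and not by hours. Muscle and heat shock genes were higher in the null: hsp90aa1.2 rose to 1287 ± 305 against 45.2 ± 6.42 FPKM (4.79 ± 0.80, adjusted p = 0.000684), the chaperone hsp90b1 by 2.48 ± 0.16, the myosin chain mylz3 by 2.36 ± 0.29, the troponin tnnt3b by 2.09 ± 0.33 and casp8 by 2.27 ± 0.21. The chromatin gene hmgb3a (−3.63 ± 0.20), the methyltransferase prmt1 (−3.33 ± 0.27), the protease ctsba (−3.23 ± 0.32), the egg coat gene zp3a.2 (−1.87 ± 0.22) and the cyclin ccne2 (−1.39 ± 0.17) fell. The m6A readers ythdf3 (0.92 ± 0.21) and ythdf1 (0.78 ± 0.25) rose, and with ythdf2 they were the 3 of 8 m6A erasers and readers that passed, over all genes and adjusted over the list alone. Of 12 skeletal muscle genes 6 rose and 6 did not pass (7 adjusted over the list alone; median 0.879, camera adjusted p = 0.00652, and 0.0617 with a pseudocount of 0.1; adjusted p = 0.811 with an estimated correlation). Of 16 heat shock genes 9 rose and 7 did not pass (10 adjusted over the list alone; median 0.728, camera adjusted p = 0.000101; adjusted p = 0.811 with an estimated correlation). Of 27 cell cycle genes 11 fell and 1 rose (11 and 3 adjusted over the list alone; median −0.482, camera adjusted p = 0.0076, and 0.402 after quantile normalization; adjusted p = 0.999 with an estimated correlation). Of 15 p53 response genes 8 rose (8 rose and 1 fell adjusted over the list alone; median 0.601, camera adjusted p = 0.0281; adjusted p = 0.999 with an estimated correlation). Of 25 egg genes 6 fell, over all genes and adjusted over the list alone, with a median above 0 (0.122) and a mean below it (−0.088).

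Limma passed 3664 genes at the somite stage (1704 higher, 1960 lower), and 23 (19 higher, 4 lower) without the replicate set term. Of 30 genes taken from the naming rule at this stage, 1 passed without that term. Counts without 1 library were 1597 (without maternal-zygotic null somite stage replicate 2) to 3592 (without maternal-zygotic null somite stage replicate 1), and of the genes named for this stage ythdf1 and ythdf3 did not pass each time. The majority turned without maternal-zygotic null replicate 2 (872 higher, 725 lower) and without wild type replicate 1 (1030 and 938). The log2 fold changes correlated over genes with the wild-type change from 12 to 24 h at r = 0.398.

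**Figure D4:**
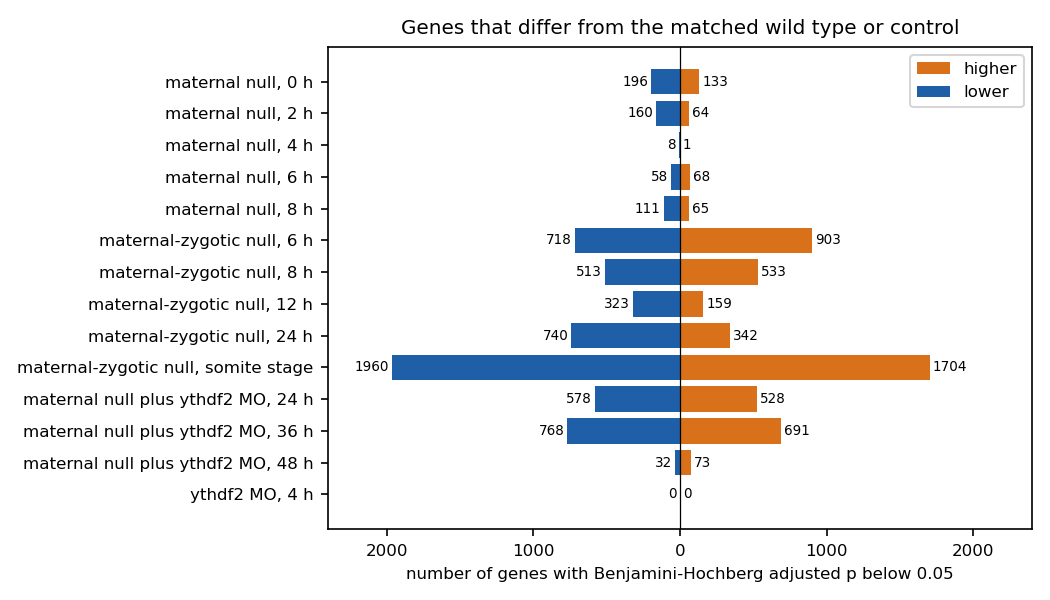
Number of genes past the adjusted threshold, higher and lower, in each comparison. The somite-stage comparison, whose groups differ in hours, passed 3664 genes.

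In maternal null embryos with ythdf2 MO, against wild type with control MO, p53 response genes were higher at 24 and 36 h. Genotype and morpholino change together here and cannot be separated. At 24 h cdkn1a (35.2 ± 1.39 against 3.268 ± 0.5001 FPKM; 3.09 ± 0.27, adjusted p = 0.000753), phlda3 (2.45 ± 0.17), mdm2 (1.84 ± 0.18) and bbc3 (1.67 ± 0.21) rose, along with the lipid droplet gene plin2 (3.96 ± 0.12), arf4b (4.02 ± 0.40), the glucose enzyme g6pca.1 (2.82 ± 0.15), the splicing factor srsf5a (2.60 ± 0.17) and isg15 (2.14 ± 0.21). The mitosis genes cdc20 (−1.14 ± 0.13) and cdk1 (−1.03 ± 0.12), the chaperones dnajb1b (−1.73 ± 0.14) and hsp70.1 (−1.26 ± 0.12), the hatching enzyme he1a (−0.95 ± 0.08), the neuronal elavl3 (−0.92 ± 0.11) and mgst3 (−1.97 ± 0.19) fell. Of 15 p53 response genes 8 rose and 7 did not pass (9 adjusted over the list alone; median 1.21, camera adjusted p = 2.79e-05; adjusted p = 0.999 with an estimated correlation). Of 26 cell cycle genes 6 fell and 20 did not pass (9 adjusted over the list alone; median −0.177, camera adjusted p = 0.0076; adjusted p = 0.999 with an estimated correlation). Of 21 deadenylation and decapping genes 4 fell and 17 did not pass (7 adjusted over the list alone; median −0.258, camera adjusted p = 0.0101; adjusted p = 0.811 with an estimated correlation). Of 7 hatching gland genes 3 fell, over all genes and adjusted over the list alone (median −0.264, camera adjusted p = 0.00847; adjusted p = 0.978 with an estimated correlation). Heat shock genes split 7 down and 2 up of 16 (7 and 4 adjusted over the list alone; no camera call, fry adjusted p = 0.000453). Among 15 neural and retina genes 2 fell and 13 did not pass (4 adjusted over the list alone).

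At 36 h g6pca.1 (80.3 ± 11.8 against 7.14 ± 1.40 FPKM; 3.32 ± 0.15, adjusted p = 9.02e-05), the collagen chaperone serpinh1b (3.06 ± 0.20), the fatty acid elongase elovl6 (2.45 ± 0.14) and plin2 (2.27 ± 0.12) were highest among the genes named, and mdm2 (1.71 ± 0.18) and tp53 itself (0.95 ± 0.19) rose. The heat shock genes hsp90aa1.2 (1.68 ± 0.12), hspa5 (1.61 ± 0.10) and hsp90b1 (1.47 ± 0.09) rose, and the complement gene cfb (−2.04 ± 0.10), anxa6 (−1.82 ± 0.10), krt5 (−1.28 ± 0.10) and the heme and globin genes urod (−0.77 ± 0.10) and hbae1 (−0.58 ± 0.11) fell. Of 7 erythroid genes 4 fell and 3 did not pass (7 adjusted over the list alone; median −0.597, camera adjusted p = 0.000436; adjusted p = 0.647 with an estimated correlation). Of 16 heat shock genes 6 rose and 10 did not pass (8 rose and 1 fell adjusted over the list alone; median 0.368, camera adjusted p = 0.00123; adjusted p = 0.647 with an estimated correlation; fry adjusted p = 4.11e-05). Of 15 p53 response genes 6 rose and 9 did not pass (9 rose and 1 fell adjusted over the list alone; median 0.822, camera adjusted p = 0.00253; adjusted p = 0.999 with an estimated correlation). Of 3 lens crystallins 2 rose, over all genes and adjusted over the list alone (median 0.882, camera adjusted p = 0.0326; adjusted p = 0.811 with an estimated correlation). Of 6 m6A writers mettl14 fell (−0.57 ± 0.11) and 4 fell adjusted over the list alone (median −0.404, camera adjusted p = 0.0399, and 0.126 after quantile normalization; adjusted p = 0.811 with an estimated correlation). Of 4 notochord and collagen genes 1 rose and 3 did not pass (2 adjusted over the list alone; no camera call, fry adjusted p = 0.00173).

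At 48 h fewer genes passed. The galectin lgals2b rose to 1027 ± 81.6 against 209.4 ± 38.03 FPKM (adjusted p = 0.000842), elovl6 by 1.73 ± 0.14, mdm2 by 1.25 ± 0.18 and apoea by 1.05 ± 0.10, and transferrin tfa (−1.35 ± 0.08), the cartilage gene lect1 (−1.89 ± 0.18), krt5 (−0.85 ± 0.10) and the leukocyte gene lyz (−0.88 ± 0.13) fell. Of 15 yolk syncytial and transport genes 4 rose and 1 fell (7 and 4 adjusted over the list alone), with a median of −0.064 and a mean of 0.098. Egg genes had a median of −0.217 (camera adjusted p = 0.0175; adjusted p = 0.837 with an estimated correlation), though limma passed 0 of 13, over all genes or adjusted over the list alone. Of 7 blood vessel and blood stem cell genes lyz fell, over all genes and adjusted over the list alone, and of 4 heart genes 1 rose adjusted over the list alone.

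Limma passed 1106 of 10966 genes at 24 h (528 higher, 578 lower), 1459 at 36 h (691 higher, 768 lower; 724 and 648 after quantile normalization) and 105 at 48 h (73 higher, 32 lower; 171 and 119 after quantile normalization). Without the replicate set term 445 (230 higher, 215 lower), 542 (281 and 261) and 46 passed. Leaving out 1 library gave 194 (without maternal null plus ythdf2 MO 24 h replicate 2) to 370 (without wild type control MO 24 h replicate 1) at 24 h, 219 (without wild type control MO 36 h replicate 2) to 377 (without maternal null plus ythdf2 MO 36 h replicate 1) at 36 h, and 21 (without wild type control MO 48 h replicate 2) to 68 (without wild type control MO 48 h replicate 1) at 48 h. More genes were higher than lower without maternal null plus ythdf2 MO replicate 1 (132 and 119 at 24 h, 203 and 174 at 36 h) and without wild type control MO replicate 2 (123 and 92, 137 and 82). All genes named for 24 h passed each time, as did g6pca.1, serpinh1b, elovl6, plin2, mdm2, hsp90aa1.2, hspa5, hsp90b1, cfb, anxa6 and krt5 at 36 h and lgals2b, elovl6, apoea, tfa and lect1 at 48 h; tp53, urod, hbae1 and mettl14 at 36 h and mdm2, krt5 and lyz at 48 h did not. At 24 h this effect and that of the maternal-zygotic null, which share no library, correlated at r = 0.115 over genes; 18 genes were higher in both (15.4 for independent lists) and 59 lower (39.5).

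Within the authors' maternal class, genes with an m6A-seq peak at 0, 2 or 4 h were set against those without. At 6 h in maternal-zygotic null embryos 383 of 2215 marked genes rose (17.3%) against 304 of 2728 unmarked genes (11.1%), and the medians were 0.264 and 0.124. This difference of 0.14 (0.237 in the first replicate set, 0.053 in the second) did not pass (camera adjusted p = 0.0731). At the somite stage 17.3% of marked and 15.3% of unmarked genes rose. In the other comparisons with risen genes the marked share was the lower: 0.0451 against 1.54% at 0 h and 0 against 0.859% at 2 h in maternal null embryos, 5.28 against 5.39% at 8 h and 1.67 against 2.90% at 24 h in maternal-zygotic null embryos, and 107 of 2158 against 203 of 2705 genes at 36 h in maternal null embryos with ythdf2 MO, for example. In maternal null embryos the difference was 0.064 at 0 h and 0.083 at 2 h. At 4 h it was 0.041 (0.006 in the first replicate set, and 0.081 in the second, whose null library had a wild-type ythdf2 level). It was −0.026 at 6 h and 0.014 at 8 h, and after ythdf2 MO alone −0.022. In maternal-zygotic null embryos it was 0.048 at 8 h, 0.008 at 12 h, −0.048 at 24 h and −0.058 at the somite stage, and in maternal null embryos with ythdf2 MO −0.022 at 24 h, −0.075 at 36 h and 0.032 at 48 h. None of these 14 differences passed, with or without an estimated correlation. With 1 library left out the difference at 6 h in maternal-zygotic null embryos lay between 0.042 and 0.213. Most of the others changed sign for at least 1 library, and matching marked and unmarked genes on wild-type FPKM at 0 h turned the somite-stage difference to 0.22. Over all genes at 36 h, m6A-marked genes lay lower (median −0.092, 187 up and 455 down of 4375, 207 and 499 adjusted over the list alone, camera adjusted p = 0.00256; adjusted p = 0.999 with an estimated correlation). Marks and classes are the authors' own and need expression to be seen, so these contrasts are not independent evidence.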

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

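The explanations weighed in this part and the tests set against them were chosen after the results were seen. Quantile normalization and the tests of a difference between groups had been planned.

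The library labelled maternal null 4 h replicate 2 had a wild-type level of ythdf2. Over 285 genes that differed at 0 and 2 h in a fit without the 4 h libraries, its median signed difference from wild type was −0.027, against 1.462 in replicate 1 at 4 h, which a wrong label or embryos of another genotype could give. A swap with the wild type 4 h library of the same set is argued against, since only 13% of these genes lay closer to the null there. Transcription of ythdf2 by the embryo itself is argued against too, with 17.2% of these genes closer to the null in this library and 92.3% in replicate 1. Whether the embryos or the label differ stays open.

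At the somite stage 3664 genes differed, and the groups were collected 1.5 h apart. The fold changes followed the wild-type change from 12 to 24 h at r = 0.398, against 0.12 and 0.123 for the 6 and 8 h effects, so the hours may account for a part. Of 1980 genes past the threshold for the somite-stage effect and for this wild-type change, 88.2% shared their sign. After quantile normalization 4837 genes passed. It raised the count in every maternal and maternal-zygotic null comparison, so this count cannot decide on the authors' scaling. Without the term for the replicate set 23 genes passed. The labels match the groups by somite stage, so more hours need not mean a later stage, and with no comparison at equal hours an effect of ythdf2 loss cannot be told apart.

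At 4 h maternal genes lay higher and zygotic genes lower after ythdf2 MO and in maternal null replicate set 1. Slower decay of m6A-seq-marked maternal mRNA alone is argued against by a median after MO of 0.088 in 2801 unmarked maternal genes, against 0.065 in marked ones. The 1306 unmarked genes with an entry for m6A peaks lay at 0.087. These 1306 have a peak by m6A-CLIP or at another time. The contrast therefore cannot decide on slower decay of m6A-bearing maternal mRNA in general. Less zygotic RNA raising all other FPKM should raise semi-stable genes too, and these lay at 0.064 beside maternal genes at 0.298 in set 1. This argues against it only if semi-stable genes receive no zygotic RNA of their own, which was not tested. For slower or younger embryos, r with the wild-type change from 0 to 4 h was taken within each class, for MO replicates 1 and 2 and null set 1: −0.22, −0.258 and −0.184 in maternal genes and −0.088, −0.177 and −0.25 in zygotic genes. With the weakest of these too near 0 to decide, a slowed embryo stays open beside a slowed clearance.

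The change since 0 h differed between maternal null and wild type for the following genes, which stood out because a test of the difference between the groups passed. From 0 to 6 h the difference was 4.648 for phlda3, 3.366 for foxo3b, 3.144 for isg15 (listed at 0 in both maternal null libraries at 0 h), 3.585 for shisa2, 2.238 for lmo2, −4.368 for dmrt2a, −3.419 for eva1ba and −2.349 for msgn1. From 0 to 8 h it was 3.603 for phlda3, 3.115 for foxo3b, 2.355 for bbc3, 2.937 for isg15, 3.64 for shisa2, 3.73 for creb3l3l, −3.479 for tfap2a, −4.335 for dmrt2a, −3.552 for tmsb4x, −2.925 for apoa4b.1, −2.74 for serpina1l, −2.6 for serpina1 and −3.667 for eva1ba. For dmrt2a, tfap2a, tmsb4x and shisa2 the groups already differed in the 0 h RNA. With each library left out in turn isg15, lmo2, dmrt2a and msgn1 at 6 h and bbc3, isg15, tfap2a, dmrt2a, tmsb4x and creb3l3l at 8 h lost their call at least once.

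The maternal-zygotic effect differed from the maternal effect at 6 h for hsp70l (−5.807), hsp70.1 (−5.799) and aanat1 (−3.199), and at 8 h for isg15 (−2.925), mid1ip1b (3.925) and pth2r (−6.027), by a test of that difference. None passed with every library left out in turn.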

How the results depend on the processing

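Alternatives fixed before the values were seen were the pseudocount, the filter, quantile normalization of the gene tests, the term for the replicate set, leave-one-out, the estimated correlation, m6A-CLIP marks and the stricter overlap. Chosen after the data were seen were leaving out the library labelled maternal null 4 h replicate 2, the replicate block within each time, quantile normalization of the set tests, matching on wild-type FPKM, marks by both methods and the narrower unmarked group. Where a result moved, the cause was not tested unless said. Genes past the threshold are given as maternal null (mat), maternal-zygotic null (MZ), late (maternal null with ythdf2 MO) and MO comparisons with their hours.

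Quantile normalization gave 819, 439, 122, 564 and 545 genes for mat at 0, 2, 4, 6 and 8 h (329, 224, 9, 126 and 176 without it). For MZ it gave 2538 at 6 h, 1788 at 8 h, 1059 at 12 h and 2511 at 24 h (1621, 1046, 482 and 1082), for late 48 h 290 (105) and for wild type at 4 h 3763 (1652). The difference in change since 0 h passed 39 genes at 4 h, 170 at 6 h and 381 at 8 h (0, 77 and 131), and MZ minus mat 346 at 6 h and 78 at 8 h (13 and 15). Sets past the threshold were 3 for mat 6 h (1), 1 for MZ 8 h (2) and 2 for late 48 h (1).

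Without the replicate block the counts were 190, 147 and 5 for mat at 0, 2 and 4 h, 32, 14, 7, 15 and 23 for MZ at 6, 8, 12 and 24 h and the somite stage (3664 with it), and 445, 542 and 46 for late at 24, 36 and 48 h (1106, 1459 and 105). The difference in change at 6 h passed 36, MZ minus mat passed 6 and 7, and 4 sets passed for MZ 24 h (2). With the replicate block fitted within each time, mat 4 h passed 0, MZ 2433 at 6 h and 1674 at 24 h, and late 4048, 4455 and 1364.

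For the 4 h morpholino comparison the replicate block, which pairs libraries of the same number, gave 998 genes against 0 (554 higher, 444 lower), and 13 of 15 values of named genes passed only with it. Deviations of same-numbered libraries from their group means correlated at r = 0.885, but the labels do not say that they were paired. Libraries of each number also sit in separate tables, so the correlation may come from the table.

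A pseudocount of 0.1 gave 14 genes for mat 4 h, 65 for mat 8 h, 19 for the difference in change at 4 h, and 7 and 4 for MZ minus mat. Sets were 3 for mat 0 h (1), 2 for mat 6 h (1) and 1 for MZ 8 h (2), and marked minus unmarked was −0.053 for MZ 24 h (−0.048) and −0.086 for late 36 h (−0.075). With no filter mat 4 h passed 5 and the difference in change at 4 h passed 3. Leaving out the library labelled maternal null 4 h replicate 2 gave 540, 462, 187 and 214 for mat at 0, 2, 6 and 8 h, 1816 for wild type at 4 h, and 161 and 245 for the difference in change at 6 and 8 h.

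With the correlation estimated from the data, 0 sets passed in each of the 14 comparisons. With the preset these were 1, 2, 4, 1 and 2 for mat at 0, 2, 4, 6 and 8 h, 8, 2, 3, 2 and 4 for MZ at 6, 8, 12 and 24 h and the somite stage, 4, 6 and 1 for late, and 5 for MO. All 45 set calls rest on the preset correlation.

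With 1 library left out the counts ranged from 42 to 380 (mat 0 h), 7 to 166 (2 h), 0 to 336 (4 h), 45 to 101 (6 h) and 63 to 117 (8 h). They ranged from 832 to 1805 (MZ 6 h), 251 to 618 (8 h), 68 to 172 (12 h), 435 to 811 (24 h) and 1597 to 3592 (somite stage), and from 194 to 370 (late 24 h), 219 to 377 (36 h) and 21 to 68 (48 h). MO stayed at 0. Wild type ranged from 0 to 36 (2 h), 800 to 1492 (4 h), 5478 to 6160 (6 h) and 6102 to 6616 (8 h). The difference in change ranged from 0 to 142, 15 to 114 and 33 to 157, and MZ minus mat from 5 to 32 and 2 to 18. A lone library was assumed to vary like the other groups.

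Marked minus unmarked ranged, with 1 library left out, from 0.056 to 0.089 (mat 2 h), −0.014 to 0.083 (4 h), −0.1 to 0.041 (6 h) and −0.033 to 0.081 (8 h). For MZ it ranged from −0.047 to 0.128 (8 h), −0.018 to 0.035 (12 h), −0.113 to 0.006 (24 h) and −0.111 to 0.015 (somite stage). For late it ranged from −0.031 to −0.012 (24 h), −0.087 to −0.061 (36 h) and 0.028 to 0.035 (48 h), and for MO from −0.109 to 0.047.

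By m6A-CLIP marks the difference was 0.037 (mat 2 h), −0.033 (MZ 24 h), −0.055 (late 36 h) and 0.028 (late 48 h). Marked by both methods against neither it was −0.053 (MZ 24 h), −0.094 (late 36 h) and 0.04 (late 48 h). Matched on wild-type FPKM at 0 h (1363 genes per group in 20 bins) it was 0.049 (mat 2 h), 0.01 (mat 6 h), 0.015 (MZ 12 h), −0.075 (MZ 24 h), 0.22 (somite stage), −0.055 (late 36 h) and 0.036 (late 48 h). With unmarked genes limited to those with a peak in another list it was 0.003 (MZ 12 h), −0.044 (MZ 24 h), −0.009 (late 24 h), −0.059 (late 36 h) and 0.026 (late 48 h).

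At an overlap of 50% of the smaller peak, m6A-CLIP peaks overlapped those of the next time in 53.53, 38.08, 30.99 and 53.44% (60.75, 45.44, 36.48 and 60.75% at 1 base).

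For the single genes named in the text, 147 of 362 values lost their call without the replicate block, 49 of 377 with a pseudocount of 0.1, 11 of 377 with quantile normalization and 424 of 1634 with 1 library left out. None changed direction with its call.

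Planned and not run were 1 fit over all mRNA-seq libraries for the MO comparison (units differ), a class FPKM minimum of 1 (the classes are the authors'), matching on the 0 h m6A-seq input, the top-scoring peaks (the lists hold no score) and both alternatives of the pull-down to input ratio.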

Other observations

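The test in this part was chosen after the result was seen.

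The wild-type level of casp8 fell from 20.8 ± 0.967 FPKM at 0 h to 1.83 ± 0.847 at 8 h (−2.97 ± 0.41), and in maternal null embryos it was 19.6 ± 1.75 at 8 h. The polyA nuclease parn fell from 239.6 ± 92.0 to 19.7 ± 10.8 FPKM over the same hours (−3.59 ± 0.46), and the T-box factor eomesa from 76.0 ± 41.6 to 0.975 ± 0.299 (−5.18 ± 0.34).

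The genes that differed at 0 and 2 h may be linked to the ythdf2 locus in the mothers, as variants kept beside it. At most 3.23% of the genes past the threshold were among the 100 tested genes nearest to ythdf2. With 279 placed genes past the threshold at 0 h and 186 at 2 h, 100 neighbours could hold only a part of them. The share was therefore capped and cannot decide on variants close to the locus as the main cause. Among these neighbours 1 gene passed at 0 h (2.88 for a random draw) and 6 at 2 h (1.92). Linkage over a longer stretch was not tested. A difference in strain between the mothers stays open.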
